A study of Mus musculus with 34 samples.

How the data were processed

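RNA was measured in gastrocnemius muscle of female wild-type (WT) mice and of mice with a tamoxifen-inducible whole-body deletion of Hdac4 (iRKO, exon 5 floxed). Mice were 6 months old at denervation, when the sciatic nerve of one leg was cut, and were dosed for 2 weeks with vehicle or with NVS-HD1, an inhibitor of class IIa histone deacetylases, at 10 mg/kg 2 times a day. The libraries were stranded and selected for polyadenylated RNA, per the labels' protocols. The authors deposited 1 table of TPM, a transcript abundance scaled for length and library total, with 23737 rows, each carrying a gene symbol, and 34 libraries. The values of each library add up to the fixed total of the TPM scale. Per the submitters' processing notes, STAR 2.4.5a and the mm10 build were used. The counting tool, the annotation and any filter are not given in the sources used here. TPM keep no read depth, so the depth of each library is unknown and no interval for counting error can be given.

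Libraries were grouped by genotype, treatment and leg as the labels give them: 8 contralateral control legs of vehicle-treated WT mice (WT_VEH_CON), 7 denervated legs of vehicle-treated WT mice (WT_VEH_DEN), 10 denervated legs of WT mice on NVS-HD1 (WT_NVS_DEN) and 9 denervated legs of vehicle-treated iRKO mice (iRKO_VEH_DEN). Replicates were numbered in accession order and were never paired, because the labels do not tie legs to mice. Some control and denervated legs may therefore come from the same mouse. Where the labels do not say that libraries came from separate mice, p-values measure only the spread between these libraries. The table held no control legs of NVS-HD1 or iRKO mice.

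The symbols were checked against the values after 1 exploratory fit, and the checks showed that they did not belong together. Several rows carrying symbols of highly expressed muscle genes were at 0 or at a few TPM, although the highest mean among rows labelled as fast fibre genes was 104.7 TPM, and rows with housekeeping symbols were expressed about as often as all rows. The positions of the most abundant rows were compared by eye with 2 other orders of the symbols, by Entrez number and by Entrez number sorted as text, and neither matched. Rows were not assigned to genes. The report therefore counts rows and gives their values without naming genes. The rule for named genes took, per comparison, Hdac4 and the other class IIa histone deacetylases, the 8 largest rises and the 8 largest falls at an adjusted p under 0.05 among rows with a mean of at least 2 TPM in the higher group and no provisional symbol, and members of called lists. With symbols that do not belong to the values this rule picks rows partly at random, so 2 example rows are described without symbols: those with the largest rise and the largest fall under denervation over all rows tested, which the rule also picks. The 38 gene lists and the planned check of the deleted gene cannot be read as biology, and their values serve only as checks of the labels. The symbols printed in the report were chosen after their values were seen, apart from Hdac4 and the lists.

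Values were analysed as log2(TPM + 1), so fold changes understate the change of rows with low TPM. Rows with at least 1 TPM in at least 7 libraries were tested, which left 13108 rows. All 4 groups entered 1 limma fit (limma 3.58.1 in R 4.3.3) with an empirical Bayes trend, and 6 contrasts were tested two-sided with Benjamini-Hochberg adjustment at 0.05. In the text, changed, rose, fell, higher and lower refer to rows past this threshold. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. A denervation index placed each library between the control mean (0%) and the WT_VEH_DEN mean (100%), from the rows changed at least 2-fold by denervation. Its 2 ends are fixed by construction. Measures per library were compared with exact two-sided permutation tests (Python 3.11.15, numpy 2.4.6).

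Comparisons that share the WT_VEH_DEN libraries were set beside 100 simulations without effects, made by permuting the residuals of whole libraries, and were recomputed over 70 uses of the splits of these 7 libraries into 3 and 4. The limma fit was tested on simulated data of 13108 rows, in 1 draw per comparison, with 100 rows changed at each of 2 folds. At a log2 fold of 1, the fit called 95 of 100 changed rows for denervation, 94 for NVS-HD1, 100 for the knockout and 96 for NVS-HD1 against the knockout. At a log2 fold of 0.5 it called 59, 52, 70 and 72 of 100. These 4 simulations also called 4, 0, 0 and 6 of the unchanged rows. For NVS-HD1 and for the knockout against control, 95 and 97 of 100 rows were called at a log2 fold of 1 and 66 and 78 at 0.5, and the first of these called 2 unchanged rows. The simulation of iRKO_VEH_DEN minus WT_VEH_CON called 3047 unchanged rows, whereas 12 were called when residuals were permuted separately in each row. Rows that vary together across libraries can thus give bursts of false calls: with no row changed, 3 of 100 draws gave over 100 calls for NVS-HD1, with 2746 at most, and 1 draw did so for the knockout, with 1946.

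The gene lists, the main settings and the following alternatives were fixed before the data were examined, the alternatives for part of the results and applied to the others afterwards: pseudocounts of 0.1 and 5, no filter, at least 5 TPM in 7 libraries, median-of-ratios scaling, quantile normalization, rescaling without the 20 most abundant rows, a fit of only the 2 groups compared, robust eBayes, arrayWeights, and leaving out each library in turn. The table held no symbols of mitochondrially encoded genes, so the rescaling removed the 20 rows alone. Alternatives chosen after seeing the data were leaving out 5 libraries beyond 1.5 SD on the first within-group component, leaving out the 3 iRKO_VEH_DEN libraries whose 20 most abundant rows held more TPM than in the lowest control library, 2 scalings with split WT_VEH_DEN libraries, a split of the WT_VEH_CON libraries into 4 and 4, that component as a covariate, the middle number of the code in each library's title as a term, an index chosen and scaled on different libraries, and a ranking of rows by control mean. The abundance classes were first ranked by control mean. The ranking by the mean over all libraries replaced it after those values had been seen, and both are given.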

Results

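Polyadenylated RNA of gastrocnemius muscle was profiled in 34 libraries of female mice: 8 control legs and 7 denervated legs of vehicle-treated WT mice, 10 denervated legs of WT mice given NVS-HD1, and 9 denervated legs of vehicle-treated HDAC4 iRKO mice. Between 11607 and 12933 rows of the table reached 1 TPM in a library. The median correlation of log2(TPM + 1) was 0.985 between libraries of a group and 0.964 between libraries of different groups. The highest correlation of any pair was 0.992, and 0 pairs were identical.

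The gene symbols of the table could not be used. Acta1 and Ttn, which encode skeletal actin and titin of the sarcomere, and Tnnc2, a fast troponin, labelled rows at 0 TPM in all 34 libraries. The row labelled Ckm, the muscle creatine kinase, had a mean of 7.91 TPM, and the row labelled Myh4, a fast myosin, 4.99 TPM. The row with the highest mean, 51113 TPM, carried the symbol Rnf146, and a row at 30624 TPM carried that of an olfactory receptor pseudogene, Olfr947-ps1. Of 161 rows labelled as ribosomal protein, proteasome, oxidative phosphorylation, TCA cycle or glycolysis genes, 87 (54.04%) had a mean of at least 1 TPM, and 21 were at 0 in all libraries. The share was 52.93% over all rows and 54.04% over 1114 rows labelled as olfactory receptors. Rows labelled as vomeronasal receptors differed from this, with 16.93% of 319 rows. So did those labelled as microRNAs, with 59% of 1078 rows and a median of 2.877 TPM. This median lay at the 99.97 percentile of the medians of random lists drawn from the whole table. At the end of the table, 15.9% of the last 3537 rows reached 1 TPM against 59.4% of the 20200 rows before them. This cut was placed where the shares before and after it differed most, so their contrast is the largest of those tried. The shares of both label groups lie near those of these stretches, and label and position were not separated. The row labelled Hdac4 had 17.1 ± 1.38 TPM (SD, n = 9) in iRKO_VEH_DEN and 17.2 ± 1.5 TPM (SD, n = 7) in WT_VEH_DEN (exact permutation p = 0.8704), which checks neither the deletion nor the labels of the libraries. Camera called 0 of 34 gene lists in any of the 6 comparisons, with a preset or an estimated correlation (smallest adjusted p 0.2162 and 0.974). Over the 204 tests, 9 had an unadjusted p under 0.05 with the preset correlation, where chance gives 10.2, and 0 had one with the estimated correlation. Fry, which does not compare a list with other rows, called 26 lists for denervation, 11 for NVS-HD1, 12 for the knockout and 0 for NVS-HD1 against the knockout.

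**Figure D1:**
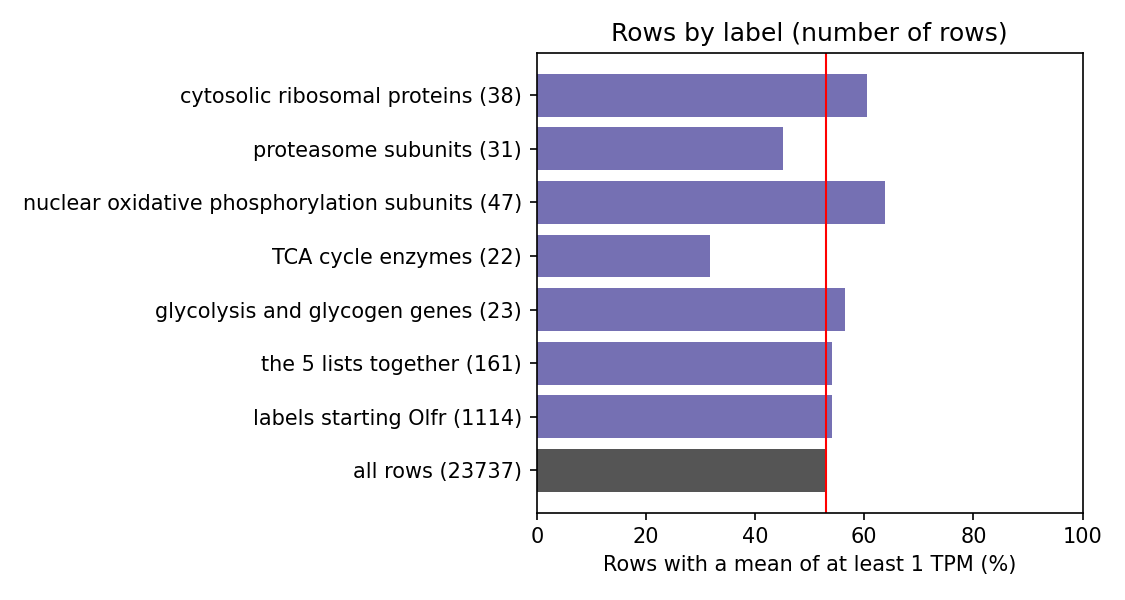
Percent of rows with a mean of at least 1 TPM over 34 libraries, by the gene symbols the rows carry, with the number of rows in brackets. The red line marks all rows at 52.93%, and the 5 housekeeping lists together lie at 54.04%.

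Denervation was examined by comparing WT_VEH_DEN with WT_VEH_CON. Of 13108 rows tested, 7996 changed, 5495 upward and 2501 downward, and 1103 rose and 471 fell at least 2-fold. One example row, that with the largest rise, went from 1.88 ± 0.707 TPM (SD, n = 8) to 520.5 ± 161 TPM (SD, n = 7), a log2 fold of 7.48 with an SE of 0.564 (limma, adjusted p = 1.81e-13). A second, that with the largest fall, went from 307.8 ± 16.0 TPM (SD, n = 8) to 8.23 ± 2.01 TPM (SD, n = 7), a log2 fold of -5.09 with an SE of 0.304 (limma, adjusted p = 8.31e-16). Neither row had overlapping values between the libraries of the groups. The excess of rises depended on the scaling. The median log2 fold over all rows was 0.17 as deposited and 0.00077 after median-of-ratios scaling, which gave 4146 rises and 3927 falls. Quantile normalization gave 3994 and 3943, and rescaling without the 20 most abundant rows gave 3986 and 3978. Within title number 29, 3 denervated libraries against 5 control libraries, 6709 rows were called, and number 28 held 1 control library, too few for a value. The title number is a number in the code of each library's title, whose meaning the labels do not give.

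The 20 rows with the highest mean held 38.7% ± 2.35 of all TPM (SD, n = 8) in control muscle and 28.5% ± 2.65 (SD, n = 7) in denervated muscle (exact permutation test, adjusted p = 0.0004114), with 36.5% to 44.1% in control libraries and 25.98% to 33.7% in denervated ones. Of these 20 rows, 13 fell and 3 rose with denervation. Rows with a mean of 10 to 100 TPM rose more often than they fell, 3035 against 1107 of 5999. Among 88 rows of at least 1000 TPM, 32 rose and 40 fell. When rows were ranked by their control mean, 12 rose and 55 fell among 81 such rows.

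The effect of NVS-HD1 in denervated muscle was examined by comparing WT_NVS_DEN with WT_VEH_DEN. NVS-HD1 changed 5198 rows, 2420 higher and 2778 lower, of which 211 and 216 changed at least 2-fold. The first example row fell from 520.5 TPM to 51.7 ± 22.2 TPM (SD, n = 10), with a log2 fold of -3.355 and an SE of 0.537 (limma, adjusted p = 5.19e-06). The second rose from 8.23 TPM to 71.2 ± 21.3 TPM (SD, n = 10), with a log2 fold of 2.94 and an SE of 0.29 (limma, adjusted p = 6.42e-10). The 20 most abundant rows held 34.8% ± 1.51 of all TPM (SD, n = 10), above WT_VEH_DEN (exact permutation test, adjusted p = 0.0004114). Of the rows called, 46.56% were higher as deposited, 47.04% after median-of-ratios scaling, 46.92% after quantile normalization and 69.37% after rescaling without the 20 most abundant rows (4205 higher, 1857 lower). With the title number as a term, 510 rows were called, and the log2 folds of the example rows were -2.496 (limma, adjusted p = 0.232) and 2.278 (limma, adjusted p = 0.0421), so that the first was no longer called. A single NVS-HD1 library, replicate 4, shared a number with any WT_VEH_DEN library, too few for a value within the number, and the median SE rose from 0.114 to 0.251 under this term. That library is also 1 of 5 far out on the first within-group component, at a score of -33.8.

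HDAC4 knockout was examined by comparing iRKO_VEH_DEN with WT_VEH_DEN. The knockout changed 5398 rows, 2001 higher and 3397 lower, of which 243 and 311 changed at least 2-fold. The first example row was lowered from 520.5 TPM to 57.5 ± 77.0 TPM (SD, n = 9), with a log2 fold of -4.12 and an SE of 0.549 (limma, adjusted p = 1.9e-07). The second was raised to 125.5 ± 94.2 TPM (SD, n = 9), with a log2 fold of 3.45 and an SE of 0.296 (limma, adjusted p = 3.15e-11). The 20 most abundant rows held 36.7% ± 3.67 of all TPM (SD, n = 9), above WT_VEH_DEN (exact permutation test, adjusted p = 0.0005245). The share of called rows that were higher was 37.07% as deposited, 47.12% after median-of-ratios scaling, 47.39% after quantile normalization and 65.51% after rescaling without the 20 most abundant rows. With the title number as a term 161 rows were called, and neither example row was, at log2 folds of -3.012 (limma, adjusted p = 0.206) and 2.603 (limma, adjusted p = 0.0644). No iRKO library shared a number with a WT_VEH_DEN library, so no value within a number can be given. The term separates number and knockout only by way of the NVS-HD1 libraries, of which replicate 4 alone shares a number with WT_VEH_DEN. The knockout values under this term thus hang on that single library, which lies far out on the first within-group component. The median SE rose from 0.1165 to 0.2886 under the term. In iRKO_VEH_DEN replicates 3, 7 and 8 the 20 most abundant rows held 40.9% to 41.8% of TPM, and in the other 6 libraries 32.4% to 35.9%. Without these 3 libraries, a choice made after their values had been seen, 4622 rows were called for the knockout, 2121 higher and 2501 lower.

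**Figure D2:**
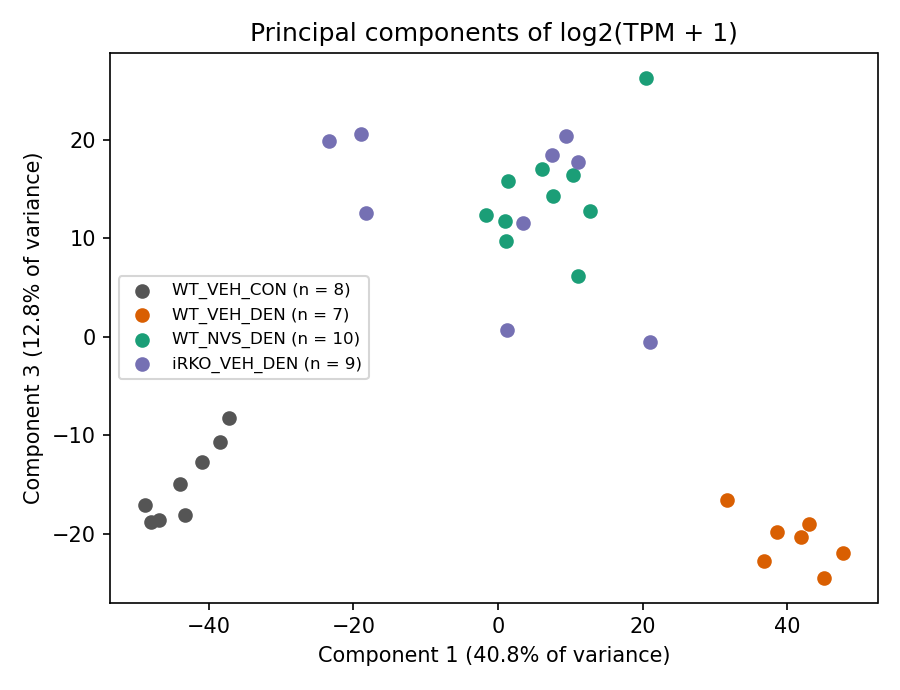
Components 1 and 3 of log2(TPM + 1) over 13108 rows, 1 point per library, holding 40.75% and 12.8% of the variance. Component 1 has a mean of -43.4 in WT_VEH_CON, 40.6 in WT_VEH_DEN, 7.01 in WT_NVS_DEN and -0.776 in iRKO_VEH_DEN. Component 3 has means of -14.9, -20.7, 14.2 and 13.5 in the same order. Component 2, with 18.67% of the variance, is not shown.

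Denervation changes were then set beside the changes under each intervention, across libraries and without control legs of NVS-HD1 or iRKO mice. An intervention effect that also occurs in innervated muscle therefore cannot be told from a smaller response to denervation. Of the 7996 rows changed by denervation, 83.32% had the opposite sign under NVS-HD1 and 87.18% under the knockout, and 4009 and 4463 were called in the opposite direction. For NVS-HD1 these were 2589 rows that rose with denervation and 1420 that fell, where independent lists give 1164.6 and 461.73. For the knockout they were 3142 and 1321, where independent lists give 1424.1 and 381.79. With the title number as a term, 458 and 150 rows were called in the opposite direction, and 68.526% and 68.499% of the rows then changed by denervation had the opposite sign. In the same direction as denervation, 253 rows were called under NVS-HD1 and 157 under the knockout. The rows changed at least 2-fold by denervation lay nearer control by a median of 46.16% of that change under NVS-HD1 and 54.61% under the knockout. Of these 1574 rows, 1371 (87.1%) still differed from control in the direction of denervation under NVS-HD1 and 1270 (80.69%) under the knockout. The same control libraries chose and tested these rows, which favours agreement. When rows were chosen against 4 control libraries and tested against the other 4, a mean of 1261.1 and 1123.5 of 1608.6 rows differed so (78.4% and 69.84%). This split also leaves fewer control libraries in each test, which lowers the calls, and the 2 effects were not separated. Under the title-number term 1066 and 859 of 1688 rows differed so (63.15% and 50.89%).

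These comparisons share the WT_VEH_DEN libraries, which gives opposite signs without any effect. Simulations without effects gave mean slopes of -0.54 and -0.54 on the denervation fold changes, steeper than the observed -0.46 and -0.53, and opposite signs in up to 84.2% and 85.1% of all rows. Neither the slope nor the share of opposite signs therefore separates the observed values from no effect while libraries are shared. The covariance of the fold changes across rows was -0.24 for denervation and NVS-HD1, against -0.0099 in simulations without effects, and -0.27 for denervation and the knockout, against -0.010. The simulations called 0 rows in both comparisons of a pair, and their mean share of opposite signs was 68.8% and 68.7%, where 74.4% and 77.7% of all rows were observed. With the WT_VEH_DEN libraries split, the slope on the denervation fold changes was -0.44 for NVS-HD1 and -0.50 for the knockout, against -0.46 and -0.53 with shared libraries, and 2879.2 and 3347.5 rows on average were called in the direction opposite to denervation. The slopes were -0.2336 and -0.2311 with the title number as a term, and neither the simulations, the splits nor the independent lists hold this number fixed. Rows are not independent replicates.

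**Figure D3:**
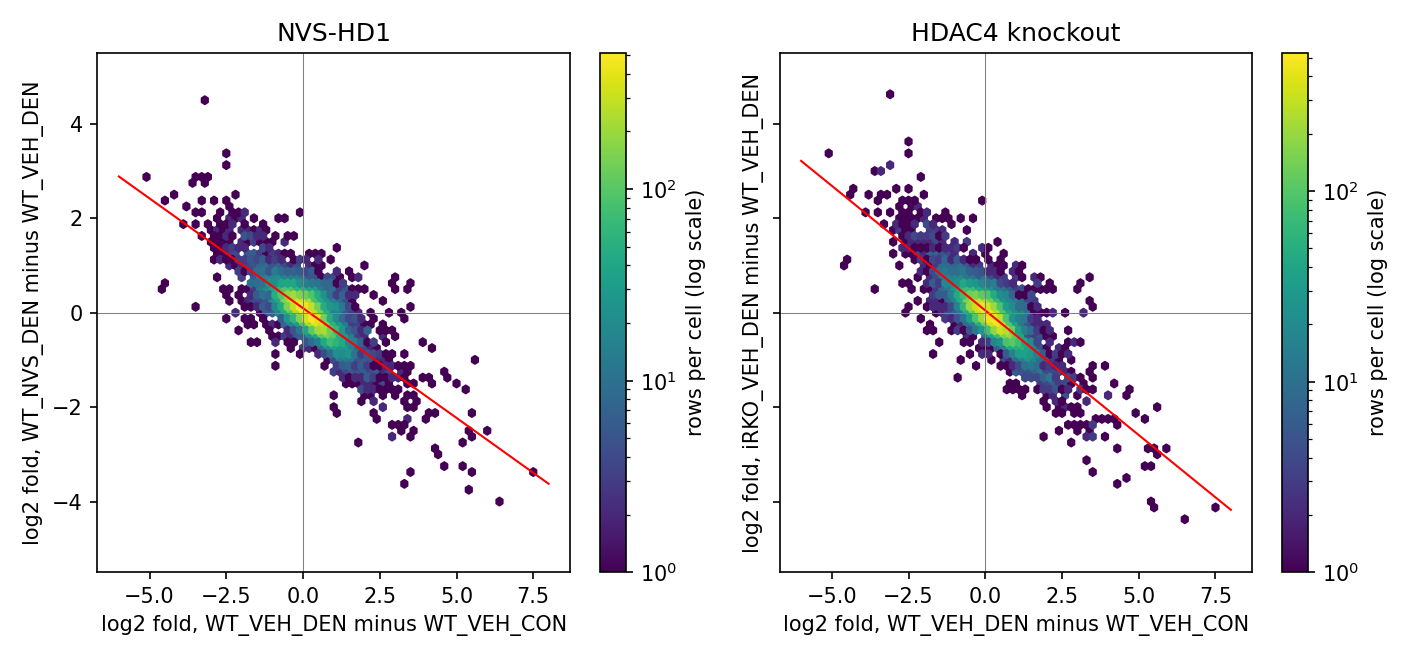
log2 fold changes of 13108 rows under NVS-HD1 (left) and HDAC4 knockout (right) against those under denervation, with cells coloured by number of rows on a log scale and the least squares line in red. The slopes are -0.46 and -0.53, and both axes share the WT_VEH_DEN libraries.

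The denervation index was 52.1% ± 8.35 (SD, n = 10) in WT_NVS_DEN and 44.9% ± 14.7 (SD, n = 9) in iRKO_VEH_DEN, a difference of 7.16 percentage points with an SE of 5.57 (exact permutation p = 0.2038). Single libraries lay between 40.6% and 64.2% with NVS-HD1 and between 21.8% and 69.8% in the knockout, where replicates 3, 7 and 8 lay between 21.8% and 32.1% and the other 6 between 47.0% and 69.8%. Without these 3 libraries the denervation index of iRKO_VEH_DEN was 53.3%.

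**Figure D4:**
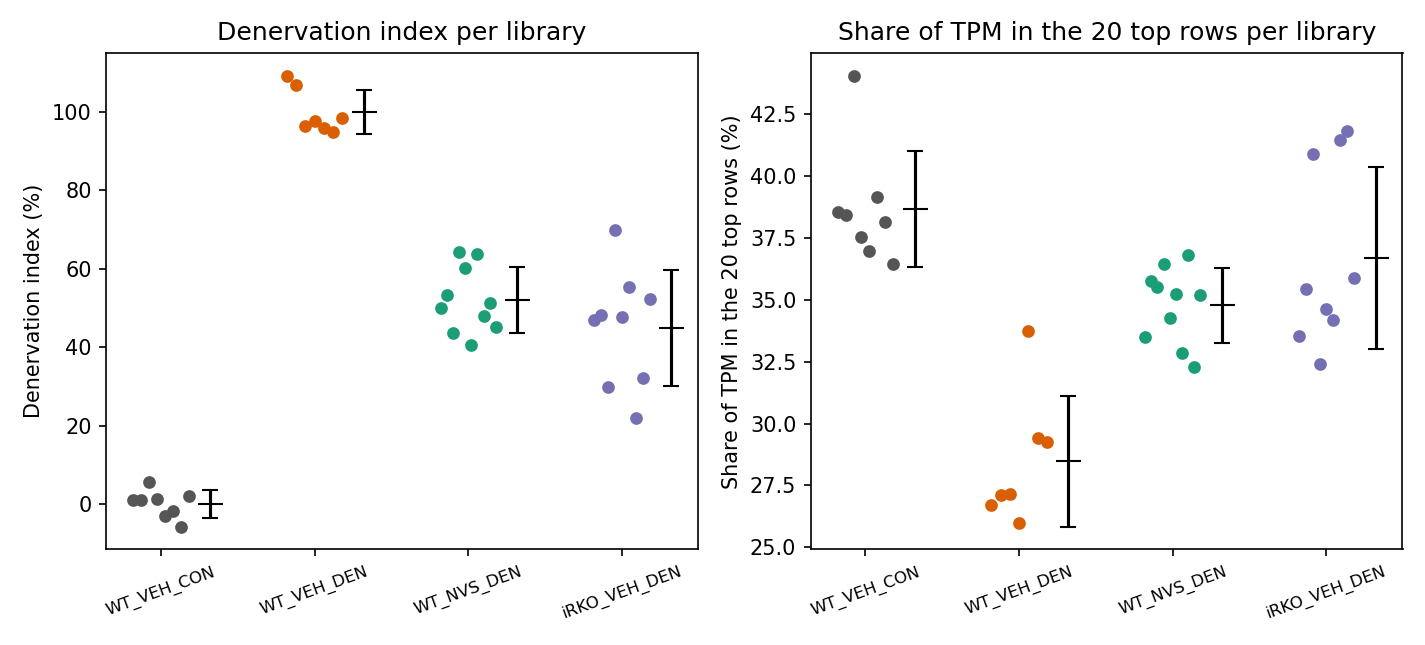
Denervation index (left) and share of TPM in the 20 most abundant rows (right) for each library, in percent, with the group mean and SD beside the points. The index is set to 0 and 100 at the means of WT_VEH_CON and WT_VEH_DEN, and its mean is 52.1 in WT_NVS_DEN and 44.9 in iRKO_VEH_DEN.

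NVS-HD1 and the knockout were compared with each other in denervated muscle. They changed 4382 rows in the same direction and 0 in opposite directions, 1745 higher and 2637 lower, where independent lists give 369.42 and 719.93 and simulations without effects gave 0. The covariance of their fold changes was 0.20 against a simulated 0.010. With split WT_VEH_DEN libraries it was 0.19, and a mean of 2818.4 rows was then called in the same direction. These simulations and splits do not hold the title number fixed, and with it as a term 153 rows were called in the same direction. Of the 4382 rows, 3700 went against the denervation change and 556 were not called for denervation. The direct test called 10 rows, 8 higher and 2 lower with NVS-HD1 than in the knockout, and 1100 had an unadjusted p under 0.05. The 95% interval of the difference lay within 1.5-fold either way in 11817 rows (90.2%) and within 2-fold in 12977 (99.0%), without adjustment for the number of rows. These folds are of TPM + 1 and so understate differences of rows with low TPM. Leaving out iRKO_VEH_DEN replicate 4 gave 51 rows, leaving out replicates 3, 7 and 8 gave 3, and the title number as a term gave 0, with 545 at an unadjusted p under 0.05. Within title number 26, 2 NVS-HD1 against 2 iRKO libraries, and number 27, 7 against 2, limma called 0 rows. Unadjusted p was under 0.05 in 717 and 814 rows. With so few libraries, 0 calls cannot be read as agreement. Chance alone gives on average a share of 0.05 of the 13108 rows tested. That number lies above the 545 rows and below the 717, 814 and 1100 rows.

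Both interventions were also compared with control muscle. WT_NVS_DEN differed from WT_VEH_CON in 6925 rows, 5488 higher and 1437 lower, and iRKO_VEH_DEN differed in 5950, 4499 higher and 1451 lower. After median-of-ratios scaling the counts were 3298 higher and 2955 lower for NVS-HD1, and 2981 higher and 2564 lower for the knockout, and after quantile normalization 3091 and 3209, and 2885 and 2810. Rescaling without the 20 most abundant rows kept an excess of rises, with 4552 higher and 1972 lower for NVS-HD1, and 4145 and 1784 for the knockout. With the title number as a term, 3055 and 2313 rows were called. With NVS-HD1 the share of TPM in the 20 most abundant rows differed from control by -3.881 percentage points (exact permutation test, adjusted p = 0.0004114). In the knockout the mean difference from control was -1.966 points (exact permutation test, adjusted p = 0.2131). Replicates 3, 7 and 8 of the knockout lay above the lowest control library, at 36.5%, and the other 6 below it.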

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

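The tests of whether labels and values stand in different row orders, of another tissue, of a separate reordering in each library and of a part of the labels being in register were written after the mismatch had been seen, and the test of scaling with split libraries was chosen after the shared-library values had been seen. Control library WT_VEH_CON replicate 3 stood far from the other 7 of its group in 3 of the 6 measures checked. Its 20 most abundant rows held 44.07% of TPM against 36.46% to 39.16% in the others, its median correlation with its group was 0.9678 against 0.9843 to 0.9902, and its score on the first within-group component was -53.94 against -2.132 to 14.45. Over the 24 groups and measures checked, chance gives about 1.2 such values, and these 3 measures of 1 library are not independent. The first within-group component held 38.22% of the variance within groups, and 32.15% after median-of-ratios scaling. The title number had a permutation p of 0.1692 for this component, which leaves it open, since a p over the threshold excludes nothing and the bound set beforehand was wrong in this.

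The 10 rows that differed between NVS-HD1 and the knockout came from a test of the difference itself. Of 100 splits of these 19 libraries, 3 gave as many rows, the real one included, which is under the 0.05 level set beforehand. So few splits place this share only roughly, and chance stays open for these 10 rows. The splits do not hold the title number fixed, which the groups share unequally. With this number as a term limma called 0 rows, with 545 at an unadjusted p under 0.05. These are fewer than the share of 0.05 of 13108 rows that chance gives on average. Another split gave 2198 rows, and what that split follows was not tested. For denervation 1 of 100 splits gave as many as the 7996 rows (highest other 6370), for NVS-HD1 1 of 100 as many as 5198 (349), for the knockout 1 of 100 as many as 5398 (4102), for NVS-HD1 against control 1 of 100 as many as 6925 (2863) and for the knockout against control 1 of 100 as many as 5950 (2153). In each of these 5 comparisons only the real split reached its count, which argues against chance at the 0.05 level set beforehand. A share under 1 of 100 cannot be resolved with 100 splits, and the title number was again not held fixed.

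The mismatch of symbols and values was weighed against 5 explanations, of which a constant shift is argued against by the best of 47470 shifts in both row orders, which brought 74.53% of the housekeeping rows to 1 TPM, and another tissue by the 53.62% reached by rows labelled as ribosomal or proteasome genes. The correlation of 0.98458 within groups argues against a separate reordering in each library. Of 75 rows labelled as fast fibre, slow fibre or oxidative phosphorylation genes, 8.0% reached 100 TPM against 5.519% of all rows, which argues against these labels being in register, although the same 3 lists varied together more than random lists did. Labels and values in different row orders stay open, because the 54.04% of housekeeping rows at 1 TPM against 52.93% of all rows is the observation that showed the mismatch and so is no test of them. The 16.93% of rows labelled as vomeronasal receptors and the 59% of those labelled as microRNAs depart from what a random order over the whole table gives. They lie near the 15.9% of the last 3537 rows and the 59.4% of the 20200 rows before them, a cut placed where these shares differ most. Label and position in the table were not separated, and no biological explanation was tested.

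The parallel changes under NVS-HD1 and the knockout kept 95.02% of their covariance when the WT_VEH_DEN libraries were split, which argues against the shared libraries as the cause. The number in the title code as a batch stays open. As a term beside the group it changed 0 rows by limma. An unadjusted p under 0.05 was found in 1148 rows, more than the share of 0.05 of 13108 rows that chance gives on average. But 1 NVS-HD1 library and 0 iRKO libraries share a number with WT_VEH_DEN, so number and group are separated only weakly. The bound of 0 rows set beforehand was too weak to exclude such a batch. With this term, 153 rows in place of 4382 changed in the same direction under both. The interventions themselves, which the design names, also stay open, untested against that batch.

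The partial return of denervation changes, meaning values nearer control than in WT_VEH_DEN, was weighed in the same way. Without control legs of NVS-HD1 or iRKO mice, it cannot be told from effects that do not depend on denervation. With split libraries the slope nearer to 0 was -0.43893, which argues against shared libraries as the whole cause, although simulations without effects give slopes as steep while libraries are shared. After median-of-ratios scaling at least 85.73% of the rows changed by denervation had the opposite sign. Simulations with shared libraries and without effects gave up to 85.1%, but over all rows and without this scaling. The simulations thus give no matching value for the rows changed by denervation. The share therefore decides nothing, and the bound set beforehand ignored the shared libraries. With split libraries, median-of-ratios scaling and rescaling without the 20 most abundant rows left at least 96.15% as many rows called opposite to denervation as were called without them, which argues against scaling by a few abundant rows as the whole cause. With the title number as a term the slopes were -0.2336 and -0.2311, and 68.526% and 68.499% of the denervation changes had the opposite sign. Simulations without effects, over all rows and without this term, gave means of 68.8% and 68.7%. With the term, 458 and 150 rows were still called opposite to denervation. How much of the return goes with that number therefore stays open.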

How the results depend on the processing

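Some alternatives were extended to further results. Chosen after seeing the data were those with the title number, the first within-group component and the 5 and the 3 left-out libraries. So were the scalings with split libraries, the split control libraries, the index on separate libraries and the ranking by control mean. Outside single rows, 834 of 881 combinations of result and alternative kept their size, and 47 moved. Row counts were judged by total, and scaling moved their share of rises. With the title number as a term, 510 rows were called for NVS-HD1, 161 for the knockout, 3055 and 2313 for these against control, 0 for NVS-HD1 against the knockout, 458 and 150 opposite to denervation, and 153 in the same direction under both. For 14 pairs of row and comparison, the 2 example rows among them, 664 combinations with an alternative kept their call and 8 lost it, in each case with this term. The example row with the largest rise lost it under both interventions. The slopes on denervation were then -0.2336 and -0.2311, and 68.526% and 68.499% of the denervation changes had the opposite sign in place of 83.32% and 87.18%. The wider SE under this term can lower the number of calls, whereas the slopes are computed from the fold changes without the SE. Wider SE and smaller fold changes were not separated, and the cause was not tested. The number of rows differing between NVS-HD1 and the knockout, 10, was 5 with no filter, 6 at 5 TPM or more, 5 after median-of-ratios scaling, 5 after quantile normalization, 6 after rescaling, 2 with only the 2 groups, 4 without the 5 libraries and 3 without iRKO_VEH_DEN replicates 3, 7 and 8. It was 127 with the first within-group component as a covariate, which was estimated from the same residuals and so narrows the spread by construction. Without those 3 iRKO libraries the slope of the knockout on denervation was -0.4569. The share of denervation changes with the opposite sign under the knockout was 82.665% without them and 83.685% with arrayWeights. The cause of the others was not tested.

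Leaving out each library in turn gave 5 to 51 such rows. Without iRKO_VEH_DEN replicate 4 the count was 51. It was 5 without WT_NVS_DEN replicates 2 or 8 or iRKO_VEH_DEN replicates 2 or 8, and 6 without WT_VEH_CON replicate 5, WT_VEH_DEN replicate 3, WT_NVS_DEN replicates 1, 4, 5, 9 or 10 or iRKO_VEH_DEN replicate 6. For denervation the range was 7676 to 8085 rows, for NVS-HD1 4622 to 5469 and for the knockout 4955 to 5649. Against control it was 6568 to 6987 for NVS-HD1 and 5549 to 6104 for the knockout. With split WT_VEH_DEN libraries, 2818.4 rows on average were called in the same direction under both interventions, with fewer libraries per comparison. Fry called 96 lists over the 6 comparisons where camera called 0, and it asks another question. With a pseudocount of 5, 837 of 941 rows changed at least 2-fold by denervation still differed from control in its direction under NVS-HD1 and 775 under the knockout, in place of 1371 and 1270 of 1574. The larger pseudocount shrinks the folds, so fewer rows reach 2-fold. The denervation index was 52.2% and 44.9% when rows were chosen and scaled on different libraries.

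Ranking by control mean, used first, gave 1 rise and 15 falls with denervation among the 20 most abundant rows in place of 3 and 13. Among rows of at least 1000 TPM it gave 12 and 55 in place of 32 and 40 for denervation, 45 and 8 in place of 40 and 23 for NVS-HD1, and 40 and 11 in place of 37 and 26 for the knockout. No paired analysis was possible because the labels do not tie legs to mice. TPM keep no depth, so its effect on rows with low values could not be assessed.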

Other observations

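Of the 4382 rows that changed in the same direction under NVS-HD1 and the knockout, 556 were not called for denervation, 433 of them higher and 123 lower. Changes of at least 2-fold under both interventions were found in 9 of these 556 rows. The index of the knockout libraries had a variance 3.109 times that of the NVS-HD1 libraries, which was not tested.

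Rows labelled as members of 3 of the 34 lists tested varied together within groups beyond the upper two-sided 0.05 bound of random lists, where chance gives 0.85 lists, and 0 lists lay below the lower bound. These were fast fibre genes at the 99.3 percentile, slow fibre genes at the 99 percentile and oxidative phosphorylation subunits at the 98.2 percentile. The rows labelled as these genes had no mean above 527.5 TPM. Why these 3 lists stand out was not resolved.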
